A study of Harpegnathos saltator with 35 samples.

How the data were processed

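The series measures polyadenylated RNA by strand-specific sequencing (dUTP method, per the labels' protocols) in 35 primary neuronal cultures in 8 groups: baselines in 20E and in JH3, and each culture switched to the opposite hormone for 30 min, 6 h or 24 h. Groups and replicate numbers were taken from the sample titles. The 3 sequencing runs, called A, B and C here, were read from a date and flow cell code in each sample's description. The 20E cultures given JH3 for 24 h came from run C alone, and the JH3 baseline from runs A and B.

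The authors deposited a table of FPKM values (fragments scaled to gene length and library size) for 14001 genes, with a column for each library. The processing tools were bcl2fastq, STAR, featureCounts and DESeq2, per the submitters' processing notes, with no versions. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Gene names came from a RefSeq table of assembly Hsal_v8.6, matched by gene number; 13989 of 14001 identifiers matched and 4117 had a symbol, the others being known only by number.

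Within a gene the deposited FPKM values were whole multiples of a step, which gave whole reads and a gene length for 13327 genes, including all 9873 genes tested. Of their nonzero values 100.0% were within 0.03 of a whole number of reads, and the largest distance was 4.94e-05. A further 395 genes were at 0 in every library and 279 were above 0 in too few libraries. The steps followed median-ratio size factors (spread over libraries 0.965%) and not total reads (37.2%), so the deposited values are scaled between libraries by such factors. The libraries held 5938017 to 22650451 recovered reads, and between 8855 and 9187 genes at FPKM of 1 or more. Intervals that rest on reads were not used, since the spread between cultures sets the error. The 63 pairs of replicates within a group differed by far more than sampling noise (chi-square per gene 7.17 to 177), so none was counted as a repeat deposit of another.

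Genes with FPKM of at least 1 in at least 3 libraries were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with group and run as terms over all 35 libraries, a trended prior and robust estimation. Fold changes on this scale understate the change of low genes, and since they are adjusted for run they need not equal the ratio of the mean FPKM printed beside them. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 7 comparisons were the baselines with each other and each switch at each time with its own baseline, and 6 more results were the difference between the switches and their mean at each time. All tests were two-sided.

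Before the data were examined, 20 lists of genes were fixed from textbook knowledge of insects (hormone response, neuronal function, housekeeping and other cell types), of which 19 had 3 or more tested members. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists. The genes named were fixed by a rule at the same time. In each comparison these were the 8 largest rises and 8 largest falls among called genes with a name and a mean FPKM of at least 2 in a group (all of them where fewer than 16), 11 hormone genes whatever they did, and up to 4 called members of each list. For the difference and mean of the switches these were the 5 smallest p each way. Of the 11 hormone genes Met was not among the symbols used here.

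Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at FPKM 5, median-ratio rescaling, quantile normalization, no run term, 2 sets of runs (run A against runs B and C), library weights, the replicate number as a block, fits within run A and within runs B and C, fits of only the compared groups, and leaving out each library in turn. In the fits of only the compared groups the 2 sets replaced the run term, and no such term was used where a group lacked a set. Alternatives added after the data were seen were limma's voom on recovered reads, each library's trend of expression with gene length as a covariate, and leaving out both JH3 baseline replicate 4 and replicate 5 of the JH3 cultures given 20E for 30 min.

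The fit was tested on simulated data with 200 changed genes drawn from genes with a mean log2 value above 2 and noise independent between genes, which is simpler than the real libraries. For the comparison of the baselines, run on 9873 genes, 50.00% of genes changed by 0.5 on the log2 scale, 90.00% of those changed by 1 and 100.00% of those changed by 2 were called, and 3.41% of calls were unchanged genes. For 24 h of JH3, run on 9873 genes, these were 34.00%, 78.00% and 98.00%, with 4.32% of calls unchanged genes. For 30 min of JH3 8.05% of calls were unchanged genes. Recovery of reads was exact for 100.00% of 2780 simulated genes. An estimate of the share of the baseline difference covered after a switch first returned a mean of 0.073 for a true 0.1 in 20E cultures given JH3 for 24 h, because the run term ties the contrasts together, and with that term subtracted it returned 0.098 (SD 0.007, 30 simulated data sets, 9873 genes). Other tools were Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.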

Results

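Polyadenylated RNA was sequenced from 35 primary neuronal cultures of the ant Harpegnathos saltator, made from dissociated central brains. Cultures were kept for 5 days in 2 µM of either 20-hydroxyecdysone (20E, the active moulting steroid of insects) or juvenile hormone III (JH3, the sesquiterpenoid that opposes or modifies its action at many life stages). The medium was then changed to one with 2 µM of the opposite hormone for 30 min, 6 h or 24 h, or to one with the solvent DMSO for 30 min, which served as the baseline. Libraries numbered 5 for the 20E baseline, 4 for the JH3 baseline, 5, 6 and 4 for JH3 cultures given 20E for 30 min, 6 h and 24 h, and 3, 5 and 3 for 20E cultures given JH3 for 30 min, 6 h and 24 h. The replicates are independent cultures, per the series' design text. The libraries held between 5938017 and 22650451 reads assigned to genes, with a median of 10844908, as recovered from the steps of the FPKM values. Levels below are mean FPKM ± SD over cultures, and fold changes are on the log2(FPKM + 1) scale with their standard error (SE), adjusted for 3 sequencing runs.

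The hormone of the 5 days in culture was the first axis of variation among the 35 libraries. The first principal component took 30.9% of the variance, and its mean was -22.8 ± 4.26 (SD, n = 5) in the 20E baseline and 16.6 ± 13.1 (SD, n = 4) in the JH3 baseline. JH3 baseline replicate 4 lay at -2.68, while the other 3 JH3 baseline libraries lay between 20.9 and 25.9. The second component took 20.4% and followed each library's trend of expression with gene length (Pearson r = 0.94, Spearman rho = 0.87). Both had permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give. Trend and component were computed from the same values, so this p does not show how far such a relation is built in. Without the 2 libraries farthest from the median trend r was 0.92, and within runs A, B and C it was 0.81, 0.98 and 0.96. With the first component the trend had r of 0.28, for which no p was computed. The trend differed between cultures of the same group, with SDs of 0.028 to 0.098 log2 units per doubling of gene length.

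**Figure D1:**
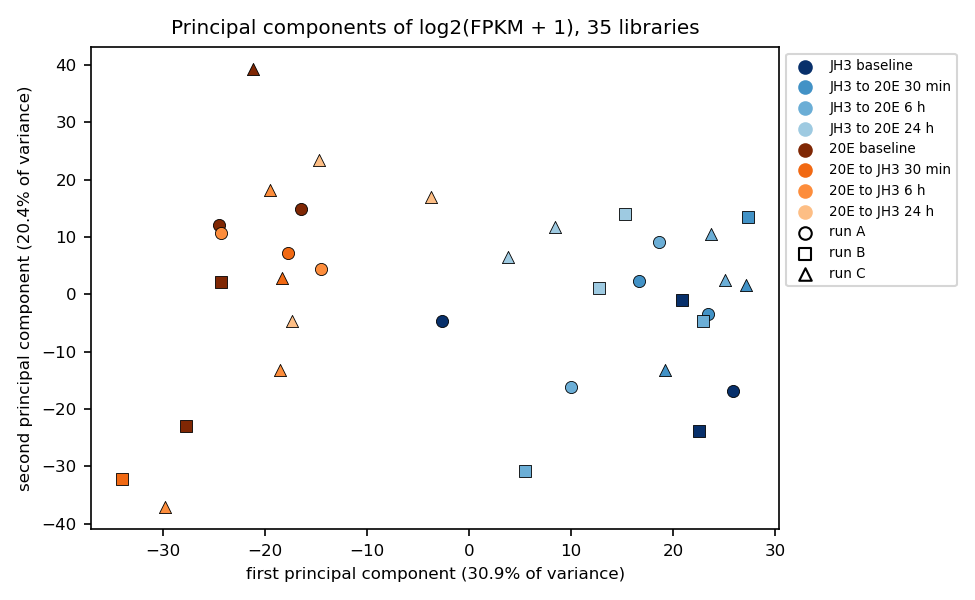
Each point is 1 of 35 libraries, placed by its first (30.9% of variance) and second (20.4%) principal components of log2(FPKM + 1), with colour for the group and shape for the sequencing run. Libraries of 20E cultures lie to the left and those of JH3 cultures to the right, with JH3 baseline replicate 4 at -2.68 between them.

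The first comparison asked which genes differed between cultures held in 20E and cultures held in JH3. Of 12 ecdysone response genes measured, 5 were higher in 20E, 3 lower and 4 did not pass the test, with the same numbers adjusted over the list alone. As a set they had adjusted p = 0.471 by camera and adjusted p = 0.853 with an estimated correlation. Hr4 (LOC105190338), a nuclear receptor of the ecdysone cascade, was at 81.2 ± 36.8 FPKM in the 20E baseline (n = 5) and 5.30 ± 2.58 in the JH3 baseline (n = 4), a log2 fold change of 3.69 (SE 0.43, adjusted p = 4.29e-07). E23 (LOC105184499), an ABC transporter known as an early ecdysone gene, was higher by 2.82 (SE 0.35), at 44.0 ± 18.6 against 5.05 ± 1.90 FPKM. The nuclear receptor Hr3 was higher by 1.46 (SE 0.21), the transcription factor Eip93F by 1.54 (SE 0.34) and the nuclear receptor E75 (LOC105187469) by 0.81 (SE 0.23), with E75 at 79.1 ± 13.6 against 45.0 ± 11.8 FPKM. In the other direction, usp (LOC105190116), the partner of the ecdysone receptor, was lower in 20E by log2 -2.34 (SE 0.26), at 9.08 ± 3.49 against 47.7 ± 11.01 FPKM. The nuclear receptor ftz-f1 was lower by -2.34 (SE 0.31), at 7.40 ± 2.70 against 42.7 ± 20.0 FPKM, and the receptor gene Ecr by -0.45 (SE 0.14). Kr-h1 (LOC112589664), the zinc finger gene that juvenile hormone induces, was lower in 20E by -1.62 (SE 0.39, adjusted p = 0.00361), at 8.40 ± 4.19 against 27.5 ± 13.3 FPKM. It was the only called member among 4 measured genes of juvenile hormone response and turnover, over all genes and adjusted over the list alone. For each of these genes except Ecr all 5 libraries of the 20E baseline lay on that side of the JH3 mean, and for Ecr 4 of 5 did. The Ecr call was lost without 20E baseline replicate 3 or 5 or JH3 baseline replicate 2 (adjusted p = 0.0727, 0.0594 and 0.127).

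Dscam2, a neuronal adhesion molecule, was higher in 20E by 2.55 (SE 0.31), at 65.2 ± 34.2 against 9.27 ± 3.00 FPKM, and the cadherin gene stan by 1.75 (SE 0.36). The receptor-like gene mthl1 was higher by 1.76 (SE 0.38) and trol, which encodes the proteoglycan perlecan, by 1.49 (SE 0.42), a call lost without JH3 baseline replicate 1 or 3 (adjusted p = 0.058 and 0.0881). Nep5 (LOC105189831), a neprilysin-type peptidase, was at 0.275 ± 0.161 FPKM in 20E and 12.6 ± 7.64 in JH3, a log2 fold change of -3.31 (SE 0.21, adjusted p = 1.69e-12). The calcium-binding protein gene Scp2 was lower in 20E by -3.07 (SE 0.29), nolo by -2.90 (SE 0.28), spab by -2.88 (SE 0.41), the muscle protein gene Mp20 by -2.70 (SE 0.33) and Drep4 by -2.46 (SE 0.19). CPR1 was lower by -2.34 (SE 0.75, adjusted p = 0.0255), at 0.827 ± 0.489 against 15.4 ± 16.5 FPKM. Its call was lost with voom (adjusted p = 0.0586), without 20E baseline replicate 4 or 5 (0.0514 and 0.0644) and without JH3 baseline replicate 2 or 3 (0.0743 and 0.226), the last with a fold change of -1.37. Of 11 genes of transmitter synthesis and transport, 4 were lower in 20E and none higher, and 5 were lower adjusted over the list alone. They included Gad1, which makes GABA (-1.71, SE 0.37; 12.5 ± 5.90 against 39.2 ± 11.6 FPKM), the vesicular acetylcholine transporter VAChT (-0.73, SE 0.17), the decarboxylase gene Ddc (-0.54, SE 0.17) and the vesicular monoamine transporter Vmat (-0.62, SE 0.22, adjusted p = 0.044). Ddc and Vmat both lost their calls without 20E baseline replicate 1 (adjusted p = 0.0606 and 0.0616) and without JH3 baseline replicate 3 (0.154 and 0.257), which left 2 of the 4. Vmat was also lost without 20E baseline replicate 2, 4 or 5 or JH3 baseline replicate 1 or 2 (0.054 to 0.113), with quantile normalization (0.0524) and with no filter on low values (0.0606). The list as a set had adjusted p = 0.0613 by camera and adjusted p = 0.853 with an estimated correlation. Of 11 general neuron markers 2 were lower and none higher, where 21.1% of all tested genes were called, the synaptic vesicle gene nSyb by -0.85 (SE 0.15) and Snap25 by -0.44 (SE 0.14), and the counts were the same adjusted over the list alone. The neuron markers as a set had adjusted p = 0.269 by camera and adjusted p = 0.853 with an estimated correlation. The Snap25 call was lost with quantile normalization (-0.28, adjusted p = 0.119), and without 20E baseline replicates 1 or 3 or JH3 baseline replicates 1 or 3 (adjusted p from 0.0599 to 0.123). Of 10 mushroom body genes, 3 were lower (Dop1R2 by -1.79, SE 0.31; Fas2 by -1.02, SE 0.23; dnc by -0.96, SE 0.21) and toy, a Pax6 gene, was higher by 0.95 (SE 0.22), with 4 lower and 1 higher adjusted over the list alone.

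Of 47 nuclear genes of the mitochondrial respiratory chain, 24 were lower in the 20E baseline and none higher (28 lower adjusted over the list alone), with a median log2 fold change of -0.47. Examples were ND-49 at 43.4 ± 15.9 against 78.4 ± 24.2 FPKM (-0.86, SE 0.22), ND-75 (-0.54, SE 0.13), ND-B14 (-0.64, SE 0.17) and ATPsynB (-0.73, SE 0.19). The set had adjusted p = 2.46e-08 by camera with the preset correlation of 0.01, and adjusted p = 0.853 with an estimated correlation. With each library's length trend as a covariate, an alternative added after the data were seen, the median was -0.36 and 31 members were lower. With quantile normalization the median was -0.44 and 17 were lower. Within run A the median was -0.47 with 0 members called by limma, and within runs B and C it was -0.42 with 1 lower. Without JH3 baseline replicate 3 ND-49, ND-B14 and ATPsynB had adjusted p = 0.0521, 0.0587 and 0.0513. The other lists with 3 or more members did not pass camera in this comparison.

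Among immune genes imd, an adaptor of the antibacterial pathway of that name, was higher in 20E by 1.02 (SE 0.14) and PPO by 0.51 (SE 0.15), while the transcription factor Rel was lower by -0.59 (SE 0.14), 3 of 7 measured and the same 3 adjusted over the list alone. Of 13 neuropeptide genes Pdf (-0.88, SE 0.28) and Nplp1 (-0.60, SE 0.21) were lower, and none passed adjusted over the list alone. Markers of other cell types went both ways. Of 9 glial genes axo was higher by 0.89 (SE 0.30) and Gs2 lower by -0.69 (SE 0.21). Of 11 muscle genes Tm1 (0.46) and Zasp66 (0.64) were higher and Mlc1 (-0.51) lower. The counts were the same adjusted over each of these lists alone. Of 7 hemocyte and matrix genes LanB2 was higher by 0.44 (SE 0.16), a call not made adjusted over the list alone. No member was called among 57 cytosolic ribosomal proteins, 6 fat body, 5 photoreceptor, 4 apoptosis, 3 cytochrome P450 or 2 ecdysteroid synthesis genes. One gene each was lower in the lists of heat shock and unfolded protein genes (Xbp1, -0.68, SE 0.15), cell cycle genes (CycE, -0.35, SE 0.11) and immediate early genes (Hr38, -1.48, SE 0.54, adjusted p = 0.0496), and of these Xbp1 alone passed adjusted over the list alone. Several of these weaker calls rested on single libraries. Without JH3 baseline replicate 1 the calls of PPO, Pdf, Nplp1, axo, Gs2, Tm1, Mlc1, Zasp66, LanB2, CycE and Hr38 were lost (adjusted p from 0.0542 to 0.227), and Pdf moved from -0.88 to -0.48. JH3 baseline replicate 3 likewise ended the calls of PPO, Nplp1, axo, Tm1, Mlc1, Zasp66, LanB2, CycE and Hr38 (0.0584 to 0.197). Without JH3 baseline replicate 2 Zasp66 and Hr38 had adjusted p = 0.0514 and 0.11. Without its replicate 4 Nplp1, Mlc1 and Zasp66 had 0.0722, 0.0715 and 0.0513. Each of the 5 libraries of the 20E baseline likewise ended the Hr38 call when left out (0.0611 to 0.098). Replicate 1 of that baseline ended the calls of Nplp1, Mlc1, Zasp66 and LanB2 (0.0749 to 0.118), replicate 2 those of axo and Mlc1 (0.0544 and 0.0657) and replicate 3 those of Pdf and CycE (0.0627 and 0.0637). Replicate 4 ended those of PPO, Pdf, Nplp1, Mlc1, Zasp66, LanB2 and CycE (0.0566 to 0.137, with Zasp66 moving from 0.64 to 0.41) and replicate 5 those of Nplp1, axo, Mlc1 and LanB2 (0.0651 to 0.103). Within run A Pdf was at -0.23 (adjusted p = 0.606), CycE at -0.17 (0.68) and Tm1 at 0.23 (0.595), though Pdf stayed called within runs B and C. Mlc1 was at -0.79 in run A (0.0727) and -0.26 in runs B and C (0.581). With no filter on low values Hr38, Nplp1, Mlc1, Zasp66 and LanB2 had adjusted p from 0.0551 to 0.0701.

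In all, limma called 2088 of 9873 tested genes between the baselines, 958 higher and 1130 lower in 20E. The count was 163 within run A, 1067 within runs B and C, 692 when only the 2 baselines were fitted, 3177 with library weights, 1387 without JH3 baseline replicate 1 and 1219 without its replicate 3. Within runs the E75 fold change was 1.26 in run A (adjusted p = 0.0792) and 0.47 in runs B and C (adjusted p = 0.249), and the fold changes of Kr-h1 and Eip93F in runs B and C were -1.12 (adjusted p = 0.194) and 0.95 (adjusted p = 0.173). In run A Ecr was at -0.30 (adjusted p = 0.385), VAChT at -0.48 (0.367), nSyb at -0.55 (0.356) and Dop1R2 at -1.14 (0.123).

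**Figure D2:**
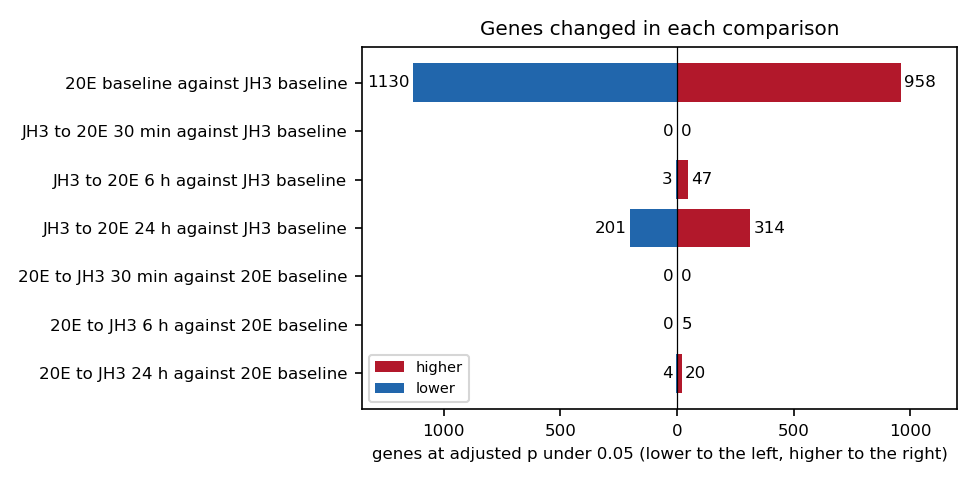
Bars give the number of genes at adjusted p under 0.05 by limma in each of 7 comparisons, higher to the right and lower to the left. The baselines differed at 958 and 1130 genes, JH3 cultures given 20E for 24 h at 515 in all, 201 of them lower, and 20E cultures given JH3 for 24 h at 20 and 4.

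The next comparisons asked how soon each culture responded to the opposite hormone. At 30 min E75 was at 46.9 ± 5.50 FPKM in JH3 cultures given 20E (n = 5), with a log2 fold change of 0.08 (SE 0.23, adjusted p = 0.999), and Hr4 was at 4.90 to 6.49 FPKM in 4 libraries and at 40.1 in replicate 5. In 20E cultures given JH3 for 30 min Kr-h1 was at 6.99 ± 1.33 FPKM (n = 3), a log2 fold change of -0.14 (SE 0.43, adjusted p = 0.907). limma called 0 genes in both comparisons, with 168 genes at an unadjusted p under 0.05 for 20E added and 1008 for JH3 added, and voom on recovered reads called 0 in both. Without replicate 1 of the 20E cultures given JH3 for 30 min, 129 genes were called, among them Eip93F at -1.49 (adjusted p = 0.0458), which was at -0.92 with it (adjusted p = 0.411). The 10 measured hormone genes of the naming rule had fold changes from -0.59 (Crz) to 0.45 (ftz-f1) for 20E added and from -0.92 (Eip93F) to 0.67 (Crz) for JH3 added.

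As sets, 8 lists passed camera with the preset correlation at 30 min of 20E and 6 at 30 min of JH3, though no member was called over all genes. With an estimated correlation none of these lists passed, with adjusted p from 0.499 to 0.527 after 20E and adjusted p = 0.605 for each after JH3. Ecdysone response genes had a median of 0.14 after 20E (adjusted p = 0.0179) and -0.29 after JH3 (adjusted p = 0.0232), which became adjusted p = 0.527 and adjusted p = 0.605 with an estimated correlation. With the length trend as a covariate these sets had adjusted p = 0.243 and adjusted p = 0.384. Within runs B and C the median after 20E was -0.09, and without the 2 libraries that stood apart, JH3 baseline replicate 4 and replicate 5 of the 30 min group, it was 0.06 (adjusted p = 0.855). Ribosomal protein genes had medians of -0.24 after 20E (adjusted p = 1.15e-08) and 0.40 after JH3 (adjusted p = 1.34e-10), and the -0.24 was -0.04 within runs B and C (adjusted p = 0.609). With the length trend as a covariate the ribosomal medians were -0.06 and 0.07, and both sets still passed camera with the preset correlation. Respiratory chain genes had medians of -0.11 (adjusted p = 5.16e-05) and 0.23 (adjusted p = 1.21e-05), the -0.11 turning to 0.03 within runs B and C. After 20E, photoreceptor (adjusted p = 1.46e-04), glial (0.0179), hemocyte and matrix (0.0361) and cytochrome P450 genes (0.0476) also passed upward and cell cycle genes downward (0.04). Of these the cell cycle set turned upward within runs B and C (adjusted p = 0.44) and without the 2 libraries that stood apart (0.637), where the P450 and hemocyte sets had 0.385 and 0.0515. Within runs B and C the glial, hemocyte and P450 sets had 0.0725, 0.12 and 0.167. With the length trend they had 0.0808, 0.243 and 0.0738, cell cycle genes had 0.0808 and respiratory chain genes 0.243. Within run A the photoreceptor set had 0.632. After JH3, heat shock and unfolded protein genes passed upward (adjusted p = 0.00732), and mushroom body (0.00678) and neuron genes (0.0374) downward. With the length trend as a covariate the neuron set had adjusted p = 0.92, the mushroom body set 0.224 and the respiratory set 0.384, with its median falling from 0.23 to 0.04. Adjusted over the list alone, 1 photoreceptor gene rose after 20E, and after JH3 2 transmitter genes rose, 1 fell and 1 muscle gene fell.

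After 6 h of 20E, JH3 cultures had raised a short set of hormone-response genes. E75 rose from 45.0 ± 11.8 (n = 4) to 488 ± 69.7 FPKM (n = 6), a log2 fold change of 3.41 (SE 0.22, adjusted p = 2.45e-11). Cyp18a1, the cytochrome P450 that inactivates ecdysteroids, rose from 0.243 ± 0.148 to 1.84 ± 0.750 FPKM (1.20, SE 0.16, adjusted p = 5.30e-05), the nuclear receptor Hr39 from 5.33 ± 0.705 to 10.8 ± 2.06 FPKM (0.87, SE 0.16) and the ETS factor gene Eip74EF from 16.9 ± 6.24 to 32.4 ± 4.58 FPKM (0.91, SE 0.20, adjusted p = 0.0205). These were the 4 called members of 12 ecdysone response genes, none fell, and 7 rose adjusted over the list alone. The set passed camera with the preset correlation (adjusted p = 1.02e-16) and with an estimated correlation (adjusted p = 0.00925), as did the 3 cytochrome P450 genes, of which Cyp18a1 rose (adjusted p = 8.05e-04 and adjusted p = 0.00925 with an estimated correlation). Cyp18a1 is a member of both lists, so the P450 set is not independent of the ecdysone set. Of 11 genes of transmitter synthesis and transport none was called, and the set had adjusted p = 0.00366, upward, and adjusted p = 0.463 with an estimated correlation. Within run A that set had adjusted p = 0.0558 and the P450 set 0.179, and without the 2 libraries that stood apart the transmitter set had 0.103. Outside that list, sing rose by 2.25 (SE 0.22), Myc, a transcription factor of cell growth, by 1.06 (SE 0.13), the diacylglycerol kinase gene rdgA by 0.96 (SE 0.17), the activin-type ligand gene Actbeta by 0.96 (SE 0.17), the chloride channel gene tty by 0.92 (SE 0.18) and tacc by 0.87 (SE 0.15). Each of these genes was above the baseline mean in 6 of 6 libraries. The clock gene per fell from 6.65 ± 2.28 to 2.96 ± 0.5679 FPKM (-0.88, SE 0.19, adjusted p = 0.0234), the ETS factor gene Ets97D fell by 0.42 (SE 0.09), and the third gene that fell was the unnamed LOC105183664 (-0.43, SE 0.10), singled out after its values were seen. Usp was at 53.0 ± 10.7 FPKM (0.11, SE 0.25, adjusted p = 0.9998) and Kr-h1 at 45.8 ± 12.9 FPKM (0.76, SE 0.38, adjusted p = 0.9998). Hr3 was at 0.61 (SE 0.20, adjusted p = 0.386), and passed with library weights (0.67, adjusted p = 0.00643).

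In total limma called 50 genes at 6 h of 20E, 47 higher and 3 lower, and 30 of the 50 had no name in the reference. The count was 4 within run A, 16 within runs B and C, 216 with library weights, 30 without JH3 baseline replicate 1 and 32 without its replicate 3. Eip74EF, at 0.91, had adjusted p from 0.0507 to 0.166 without JH3 baseline replicate 1, 3 or 4 or replicate 1, 2 or 6 of the 6 h group. The clock gene per, at -0.88, had 0.0625 to 0.226 without JH3 baseline replicate 1, 2 or 3 or replicate 1 or 4 of the 6 h group, and 0.12 with a pseudocount of 0.1. Eip74EF was at 1.37 in run A (adjusted p = 0.333) and 0.45 in runs B and C (adjusted p = 1.0). Without JH3 baseline replicates 1 and 3 in turn tty, at 0.92, had adjusted p = 0.0889 and 0.0845 and Ets97D, at -0.42, had 0.2 and 0.152. Without replicate 6 of the 6 h group Ets97D had 0.079.

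After 24 h of 20E the JH3 cultures differed from their baseline at many genes that also separated the baselines. E23 rose from 5.05 ± 1.90 to 72.6 ± 14.7 FPKM (n = 4 each), a log2 fold change of 3.82 (SE 0.38, adjusted p = 5.97e-08). E75 stayed high at 517 ± 96.0 FPKM (3.44, SE 0.25) and Hr4 rose to 51.8 ± 7.79 FPKM (3.32, SE 0.48). Dscam2 rose by 2.69 (SE 0.34), SIFR, the receptor of the neuropeptide SIFamide, by 2.27 (SE 0.41), sing by 1.85 (SE 0.24), the axon guidance ligand sli by 2.14 (SE 0.22) and the adhesion gene Nrt by 2.02 (SE 0.28). Of the 12 ecdysone response genes 7 rose, among them Hr3 (1.59, SE 0.23), Eip74EF (1.54, SE 0.22), Hr39 (1.46, SE 0.18) and Eip93F (1.30, SE 0.37, adjusted p = 0.0356), and 3 fell, usp to 19.6 ± 4.99 FPKM (-1.28, SE 0.28), ftz-f1 to 11.4 ± 3.27 FPKM (-1.81, SE 0.34) and Ecr (-0.52, SE 0.16, adjusted p = 0.0493). Adjusted over the list alone 8 rose and 3 fell. The set passed camera with adjusted p = 5.88e-06, and had adjusted p = 0.405 with an estimated correlation. Nep5 fell from 12.6 ± 7.64 to 0.610 ± 0.267 FPKM (-3.16, SE 0.23), Drep4 by -1.93 (SE 0.21), nolo by -1.92 (SE 0.31), the adenylate cyclase gene Adcy8 by -1.68 (SE 0.29), the ubiquitin ligase gene Cbl by -1.39 (SE 0.25), klu by -1.34 (SE 0.24) and Rpb8, a subunit of RNA polymerases, by -1.34 (SE 0.23). Imd rose by 1.38 (SE 0.15) and Cyp18a1 by 1.18 (SE 0.18). The glial gene Gs2 rose by 0.85 (SE 0.23, adjusted p = 0.0223), 1 of 9 in its list, as imd was 1 of 7 in the immune list. Each named change was in that direction in 4 of 4 libraries against the baseline mean. Kr-h1 was at 49.0 ± 8.33 FPKM (0.87, SE 0.43, adjusted p = 0.295), and passed with library weights (1.15, adjusted p = 0.0228). Ribosomal protein genes had a median of -0.41 with no member called, and the set had adjusted p = 5.88e-06 by camera. Respiratory chain genes had a median of -0.18, also with no member called, and adjusted p = 0.00299. With an estimated correlation both sets had adjusted p = 0.815, and within runs B and C they had 0.3 and 0.303. With the length trend as a covariate the ribosomal median was -0.03 (adjusted p = 0.643) and the direction of the respiratory set was lost, with a median of 0.02 (adjusted p = 0.966).

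limma called 515 genes at 24 h of 20E, 201 of them lower and the others higher. The count was 272 within runs B and C, the runs that hold this group, 2016 with library weights, 338 without JH3 baseline replicate 1 and 337 without replicate 1 of the 24 h group. Gs2 lost its call without JH3 baseline replicate 3 or 4 or replicate 1 or 2 of the 24 h group (adjusted p from 0.0535 to 0.0817) and within runs B and C (0.56, adjusted p = 0.213). Ecr lost its call without JH3 baseline replicate 1, 2 or 4 or replicate 2, 3 or 4 of the 24 h group (0.0622 to 0.197). Eip93F, at 1.30, lost its call without JH3 baseline replicate 3 or 4 or replicate 1, 3 or 4 of the 24 h group (0.0616 to 0.171), with no filter on low values (0.0509) and within runs B and C (0.87, adjusted p = 0.445). Ecr also had adjusted p = 0.0524 with a pseudocount of 0.1 and 0.0643 with no filter on low values. The baseline received DMSO for 30 min, so a comparison at 6 h or 24 h also holds the longer time in the changed medium. It also holds the longer time since the medium with the first hormone was replaced. At 6 h and 24 h of either switch the longer loss of that hormone and the addition of the other cannot be told apart.

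**Figure D3:**
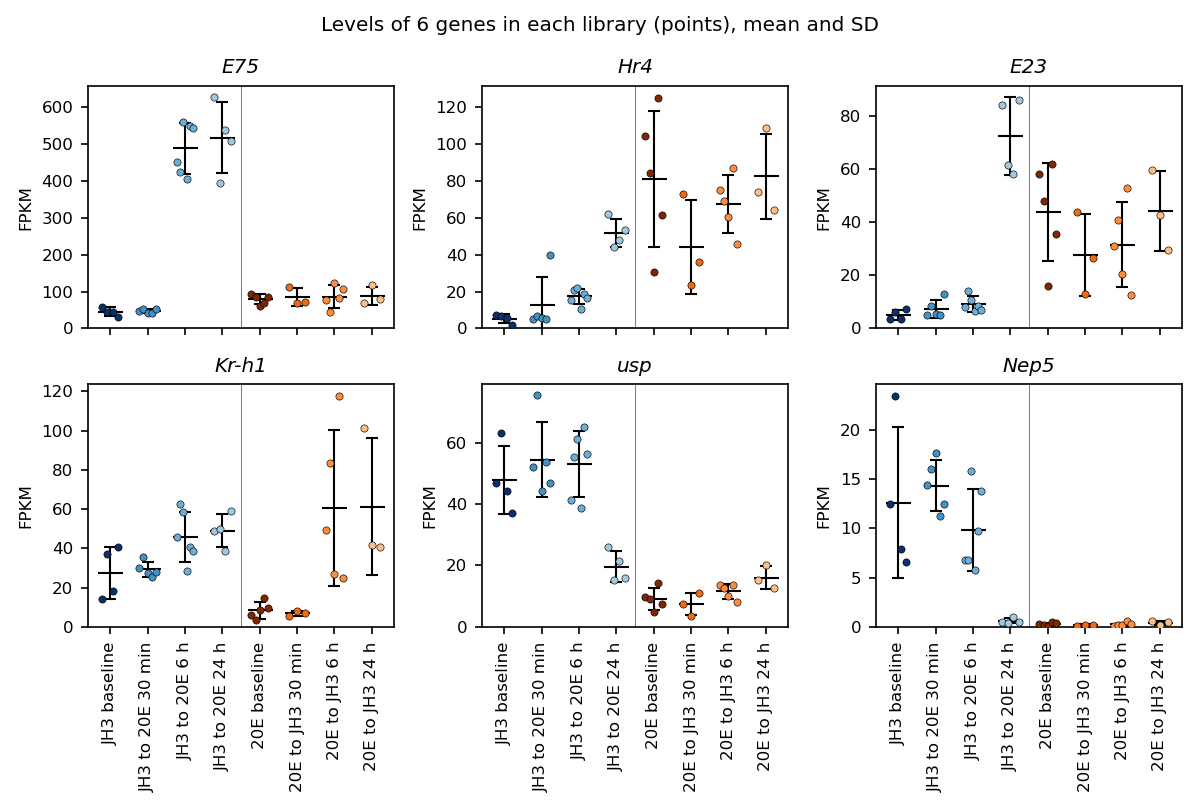
FPKM of E75, Hr4, E23, Kr-h1, usp and Nep5 in each library (points) of the 8 groups, with a horizontal bar for the mean and whiskers for the SD, on linear axes that start at 0. E75 lies between 406 and 559 FPKM at 6 h of 20E in JH3 cultures and between 30.6 and 59.4 in their baseline, while Kr-h1 lies between 25.0 and 118 at 6 h of JH3 in 20E cultures and between 3.26 and 14.5 in theirs.

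20E cultures given JH3 for 6 h raised 5 genes and lowered none. Kr-h1 rose from 8.40 ± 4.19 to 60.5 ± 39.8 FPKM (n = 5 each), a log2 fold change of 2.53 (SE 0.38, adjusted p = 8.45e-04). Sidpn, a relative of the repressor gene deadpan, rose from 13.8 ± 1.86 to 41.0 ± 6.16 FPKM (1.51, SE 0.15), cwo, a repressor of the circadian clock, from 5.56 ± 0.946 to 14.98 ± 1.52 FPKM (1.28, SE 0.15) and Pino from 43.6 ± 5.59 to 75.7 ± 5.10 FPKM (0.79, SE 0.14, adjusted p = 0.0120). The fifth was the unnamed LOC105192299, singled out after its values were seen, which rose from 0.670 ± 0.230 to 4.204 ± 1.69 FPKM (1.71, SE 0.14, adjusted p = 1.18e-08). For the 4 named genes all 5 libraries were above the baseline mean. Kr-h1 was the 1 gene that rose of 4 measured genes of juvenile hormone response and turnover, over all genes and adjusted over the list alone. Ecdysone response genes gave no call, the uncalled hormone genes of the naming rule ranging from -0.35 (br) to 0.96 (Crz), with E75 at 86.2 ± 30.7 FPKM (0.06, SE 0.22) and usp at 11.6 ± 2.39 FPKM (0.32, SE 0.25). limma called 1 gene within run A, 2 within runs B and C, 3 when only the 2 groups were fitted and 9 with library weights, and voom on recovered reads called 8. The Kr-h1 fold change was 3.57 in run A (adjusted p = 0.0516) and 1.75 in runs B and C (adjusted p = 0.385). Without 20E baseline replicate 4 or replicate 1 of the 6 h group Pino had adjusted p = 0.138 and 0.0758. Ribosomal protein and respiratory chain genes had medians of 0.46 and 0.36 with no member called, and both sets had adjusted p = 7.82e-15 by camera. Within run A these medians were 0.13 and 0.12, within runs B and C 0.75 and 0.56, and with the length trend as a covariate 0.10 and 0.14. With that covariate both sets still passed camera with the preset correlation. Hemocyte and matrix genes had a median of -0.30 with no member called and adjusted p = 0.0401, and with an estimated correlation each of the 3 sets had adjusted p = 0.794. The hemocyte and matrix set had adjusted p = 0.205 with the filter at FPKM 5, 0.0725 with no run term and 0.744 within run A, and 0.154 with the length trend.

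After 24 h of JH3 the same 5 genes were still higher, and Scp2, one of the genes lowest in 20E at baseline, was among those that joined them. Kr-h1 was at 61.3 ± 34.8 FPKM (n = 3; 2.62, SE 0.46, adjusted p = 0.00397). Scp2 rose from 23.2 ± 4.01 to 96.7 ± 52.9 FPKM (2.03, SE 0.35), Glut4EF by 1.58 (SE 0.31), Delta, the Notch ligand, from 14.7 ± 2.31 to 30.4 ± 1.84 FPKM (1.12, SE 0.20), the sodium/calcium exchanger gene Nckx30C by 1.05 (SE 0.22), Sidpn by 1.04 (SE 0.18), cwo by 1.01 (SE 0.18), Pino by 1.01 (SE 0.17) and gny by 0.52 (SE 0.11). Each was above the baseline mean in 3 of 3 libraries. The 4 genes that fell were unnamed, singled out after their values were seen, with LOC112589038 at -0.74 (SE 0.17) and LOC112589748 at -0.70 (SE 0.15) the furthest, then LOC105184447 at -0.62 (adjusted p = 0.0168) and LOC105181341 at -0.43 (SE 0.09). Kr-h1 was again the only called member among the 4 genes of its list, and no ecdysone response gene was called, with usp at 15.97 ± 3.73 FPKM (0.72, SE 0.30, adjusted p = 0.335) and ftz-f1 at 14.8 ± 1.69 FPKM (0.83, SE 0.37, adjusted p = 0.369), and the other uncalled hormone genes between -0.43 (Eip93F) and 0.32 (Eip74EF). Respiratory chain genes had a median of 0.31 with no member called (0.38 and 4 higher with the length trend as a covariate), and the set had adjusted p = 2.31e-05 by camera and adjusted p = 0.779 with an estimated correlation. For ribosomal protein genes the median was 0.24 with no member called, and these were adjusted p = 0.0246 and adjusted p = 0.831, with 0.127 under quantile normalization and 0.363 without the run term.

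limma called 24 genes at 24 h of JH3, 20 higher and 4 lower, in 3 libraries that all came from run C. The count was 6 within runs B and C, 7 when only the 2 groups were fitted, 61 without the run term, 55 with library weights, 15 without 20E baseline replicate 1, 42 without its replicate 5, and 54 and 12 without replicates 1 and 2 of the 24 h group. Scp2, at 2.03, was at 1.62 with adjusted p = 0.0693 without replicate 2 of the 24 h group, and Glut4EF, at 1.58, had adjusted p = 0.0542 and 0.108 without replicates 1 and 2. Nckx30C, at 1.05, had adjusted p from 0.0594 to 0.315 without 20E baseline replicate 1 or 3 or replicate 2 or 3 of the 24 h group. For gny, at 0.52, it was 0.0522 to 0.143 without 20E baseline replicate 1 or 4 or any of the 3 libraries of the 24 h group. In runs B and C alone Kr-h1 was at 2.12 (adjusted p = 0.165).

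The difference between the switches was tested gene by gene, as the change after 20E was added minus the change after JH3 was added. At 6 h it passed for 23 genes, 20 positive and 3 negative. E75 differed by 3.36 (SE 0.31, adjusted p = 9.88e-08), sing by 1.72 (SE 0.30), Actbeta by 1.19 (SE 0.23), Hr39 by 1.13 (SE 0.22) and Cyp18a1 by 1.13 (SE 0.22), while Sidpn differed by -1.48 (SE 0.20) and cwo by -1.46 (SE 0.20). At 24 h it passed for 298 genes, 143 positive and 155 negative, among them E23 (3.70, SE 0.53), E75 (3.36, SE 0.35), Pgm1, which encodes a phosphoglucomutase (2.24, SE 0.24), sli (2.16, SE 0.31), imd (1.74, SE 0.21), Hr3 (1.46, SE 0.32) and Eip74EF (1.21, SE 0.31) on the positive side. On the negative side were Nep5 (-3.12, SE 0.32), ftz-f1 (-2.64, SE 0.48), Cbl (-2.28, SE 0.34), the transporter gene Oatp26F (-2.17, SE 0.32), Drep4 (-2.02, SE 0.29), usp (-2.0, SE 0.39) and Ets97D (-0.99, SE 0.14). The difference for Kr-h1 was -1.77 at 6 h (SE 0.53, adjusted p = 0.368) and -1.75 at 24 h (SE 0.60, adjusted p = 0.130), so its response was not shown to differ between the switches. With library weights it was -2.05 (adjusted p = 0.0186) and -1.85 (adjusted p = 0.0329), and with the length trend as a covariate, added after the data were seen, -2.28 (adjusted p = 0.00896) and -2.03 (adjusted p = 0.00783). Eip93F differed by 1.72 at 24 h (SE 0.52, adjusted p = 0.0648), and was not called. It passed without 20E baseline replicate 3 (1.96, adjusted p = 0.015) or replicate 2 of the 20E cultures given JH3 for 24 h (2.02, adjusted p = 0.0464). At 30 min limma passed 0 genes, 936 had an unadjusted p under 0.05, and voom passed 0. The counts were 15 at 6 h without JH3 baseline replicate 3 and 36 without its replicate 4, 195 at 24 h without replicate 3 of the 20E cultures given JH3 for 24 h, and 24 at 30 min without replicate 1 of those given JH3 for 30 min. Without JH3 baseline replicate 1 Actbeta and Cyp18a1 had adjusted p = 0.0723 and 0.0742 at 6 h, and Actbeta had 0.0608 without its replicate 3. With voom on recovered reads Cyp18a1 was at 2.66 (adjusted p = 0.145), and in run A Actbeta was at 0.74 (adjusted p = 1.0). At 24 h Eip74EF had adjusted p from 0.0507 to 0.0835 without 20E baseline replicate 1, JH3 baseline replicate 3, replicate 1 or 3 of the 20E cultures given JH3 for 24 h or replicate 1 or 4 of the JH3 cultures given 20E for 24 h, and was at 0.76 within runs B and C (adjusted p = 0.367). The 6 h count was 1 within run A and 2 within runs B and C, and the 24 h count with only the compared groups fitted was 186.

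The mean of both switches can pass on changes in both or on a large change in a single switch. It passed for 25 genes at 6 h, all positive, and for 193 at 24 h, 143 positive and 50 negative. The named genes that passed at 6 h were E75 (1.74, SE 0.16), Kr-h1 (1.64, SE 0.28), sing (1.39, SE 0.16), Myc (0.83, SE 0.09) and Sidpn (0.77, SE 0.11), and none of them was called in both switches. Sidpn was at 0.03 after 6 h of 20E and 1.51 after 6 h of JH3, and Myc at 1.06 and 0.60 (adjusted p = 0.0683 after JH3). Eip74EF was at 0.60 at 6 h (SE 0.14, adjusted p = 0.0888), and passed without JH3 baseline replicate 2 (0.69, adjusted p = 0.0149) or replicate 4 of the JH3 cultures given 20E for 6 h (0.65, adjusted p = 0.0486). At 24 h E23 (1.96, SE 0.29), E75 (1.76, SE 0.19), Kr-h1 (1.75, SE 0.33), Eip74EF (0.93, SE 0.17), path (0.92, SE 0.13), Hr3 (0.86, SE 0.18), Myc (0.84, SE 0.11) and Sidpn (0.81, SE 0.13) were positive. Nep5 (-1.60, SE 0.18), Drep4 (-0.92, SE 0.16), Rpb8 (-0.91, SE 0.17), CalpA (-0.61, SE 0.10) and Snx16 (-0.35, SE 0.07) were negative. Of these Sidpn alone was called in both switches at 24 h, by 0.59 after 20E (adjusted p = 0.034) and 1.04 after JH3 (adjusted p = 0.00395). Rpb8 had adjusted p = 0.0575 without the run term. At 30 min limma passed 0 genes with 294 at an unadjusted p under 0.05, and voom passed 0. The 6 h count was 2 within run A, 5 within runs B and C and 16 without 20E baseline replicate 4, and the 24 h count was 68 within runs B and C and 127 without replicate 1 of the JH3 cultures given 20E for 24 h. Over all genes the fold changes of the switches had Pearson r of -0.27, -0.05 and 0.02 at 30 min, 6 h and 24 h, with jackknife errors over libraries of 0.40, 0.40 and 0.26. These are correlations across genes, which are not independent replicates.

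A last comparison asked how far 24 h of the opposite hormone carried a culture towards the other baseline. Of the genes that rose after 24 h of 20E, 180 were also higher in the 20E baseline, where independent lists would share 30.5, and of the 201 that fell 143 were also lower (23.01). In opposite directions the lists shared 2 and 7 genes (19.5 and 35.9 for independent lists). Of the 20 genes that rose after 24 h of JH3, 12 were lower in the 20E baseline (2.29 for independent lists). The switch and the baseline difference share the baseline libraries, so part of any such overlap comes from them. The fold changes after 20E and between the baselines had a covariance of 0.0895 and r of 0.53. In 100 simulations of noise alone, with no difference between any groups, the shared libraries gave 0.0238 and 0.53. For JH3 added these were 0.0504 and 0.39, against 0.0156 and 0.32 simulated. Noise contrasts that share a baseline correlate by design, so the simulated r does not measure how much of the observed r is shared noise. With the baseline libraries split so that the comparisons shared none, the covariance was 0.0618 for 20E added (6 splits, 0.0254 to 0.0941) and 0.0251 for JH3 added (20 splits, 0.0032 to 0.0468).

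Single genes reached the other baseline to different degrees, in a contrast added after the data were examined. After 24 h of 20E, E75 in JH3 cultures exceeded the 20E baseline by 2.63 (SE 0.23, adjusted p = 5.28e-09), at 517 ± 96.0 against 79.1 ± 13.6 FPKM, and Eip74EF by 1.43 (SE 0.21). Kr-h1 was above that baseline by 2.49 (SE 0.40) and usp by 1.06 (SE 0.26). Hr3 differed from it by 0.14 (SE 0.21, adjusted p = 0.708) and Eip93F by -0.25 (SE 0.35, adjusted p = 0.672). The 20E cultures given JH3 for 24 h share no run with the JH3 baseline, so their contrast rests on a run term estimated from the other groups. After 24 h of JH3, usp in 20E cultures lay below the JH3 baseline by log2 -1.62 (SE 0.33) and ftz-f1 by -1.51 (SE 0.40), and Hr3 lay above it by 1.59 (SE 0.26). Ecr lay at -0.54 from it (SE 0.18, adjusted p = 0.0693), and passed without replicate 1 of the 24 h group (-0.67, adjusted p = 0.0436). The broad-complex gene br and the neuropeptide gene Crz were called in none of the 15 contrasts, with fold changes from -0.35 to 0.50 and from -1.26 to 0.96. Crz, at 0.95 from the 20E baseline after 24 h of 20E (adjusted p = 0.153), passed when only the compared groups were fitted (0.92, adjusted p = 0.0175). Without JH3 baseline replicate 2 the ftz-f1 value was -1.23 (adjusted p = 0.0556), and without replicate 3 of the 24 h group it was -1.42 (adjusted p = 0.0587).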

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

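The tests of the length trend, of a library of a 20E culture or of a JH3 culture given 20E under the label of JH3 baseline replicate 4, and the subtraction of the run term in the covered share were chosen only after the results they bear on had been seen.

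Single cultures stood apart from the rest of their group in 7 of 135 groups of values tested, where chance gives about 6.8. Scp2 was at 30.2 FPKM in 20E baseline replicate 1 (20.4 to 22.1 in the other 4), and Delta at 10.8 in 20E baseline replicate 3 (14.95 to 16.5). In the JH3 baseline Gad1 was at 21.8 in replicate 1 (44.5 to 45.4 in the others), VAChT at 19.2 in replicate 4 (32.2 to 32.4) and Fas2 at 79.9 in replicate 2 (48.0 to 51.6). Eip74EF was at 23.6 in replicate 4 of the JH3 cultures given 20E for 6 h (32.1 to 36.1). Hr4 was at 40.1 in replicate 5 of those given 20E for 30 min (4.90 to 6.49), the library with the fewest reads, 5938017.

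The change after 20E and the change after JH3 differed by a test of the difference itself for 23 genes at 6 h and 298 at 24 h. Named genes at 6 h were E75 (3.36), sing (1.72), Actbeta (1.19), Hr39 (1.13), Cyp18a1 (1.13), Sidpn (-1.48) and cwo (-1.46). At 24 h they were E23 (3.70), E75 (3.36), Pgm1 (2.24), sli (2.16), imd (1.74), Hr3 (1.46), Eip74EF (1.21), Ets97D (-0.99), usp (-2.0), Drep4 (-2.02), Oatp26F (-2.17), Cbl (-2.28), ftz-f1 (-2.64) and Nep5 (-3.12).

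JH3 cultures given 20E for 24 h had 515 called genes, and 20E cultures given JH3 for 24 h had 24. At an unadjusted p under 0.05 by limma the counts were 1721 and 1159, so the gap was far smaller before adjustment. Fewer libraries from a single run do not account for all of the gap in called genes. The 2 run C libraries of the JH3 cultures given 20E alone gave 187 calls, fewer than 515 but more than 24. The length trend does not account for all of it, since with that trend as a covariate the ratio of the counts fell from 21.5 to 3.13. These explanations were tested one at a time, so whether they account for it together was not tested. A candidate explanation of biology is that 20E cultures covered a smaller part of the way to the other baseline in 24 h: the covered share was 0.37 (jackknife error 0.14) after 20E and 0.17 (0.12) after JH3, and the difference of 0.1961 had an error of 0.199, so this stays open. Before the run term was subtracted the shares were 0.37 and 0.15.

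On PC1 JH3 baseline replicate 4 lay between the JH3 and the 20E cultures. Single genes did not all follow this. E75 was at 30.6 FPKM (lowest of the other JH3 baseline libraries 44.3) and Hr4 at 1.63 (lowest 5.48). Kr-h1 was at 40.7 (highest 36.9). These values lay on the side away from the 20E baseline. Usp, ftz-f1, Scp2, Nep5 and E23 lay outside the other JH3 baseline libraries towards the 20E baseline, and Dscam2 lay among them. RNA or cells mixed in from a culture like the mean of the 20E baseline would move all genes by the same share. The median share was 0.27 over 189 genes higher in the 20E baseline and 0.64 over 277 genes lower in it. The difference of -0.3699 (bootstrap error over genes 0.0352) argues against such a mixture. Single 20E baseline libraries had shares of 0.59 to 1.23 over the genes higher there and 0.98 to 1.02 over those lower there. A mixture with a single culture far from that mean is therefore not excluded. By distance from the group mean JH3 baseline replicate 4 was within the range of the libraries of 4 other groups (3 of 20E cultures and the JH3 cultures given 20E for 30 min), but other values argue against a library of each other group under this label: the shares of 0.2685 and 0.64 were below those of each library of 20E cultures (lowest 0.58 and 0.81), and PC1 lay -4.8821 SDs of a new library from the mean of the 30 min group, where the 95% limit is 2.78. PC1 lay further still from the mean of the other JH3 baseline libraries, at -8.75 such SDs (limit 4.30), so this measure does not favour its own label either. That limit does not strictly hold, since the library was singled out for its PC1 and the SD came from the libraries left. The test above for single cultures that stood apart covered PC1 and did not flag this library on it. Over the 55 and 542 genes called without this library after 6 h and 24 h of 20E, its median response was 0.3247 and 0.404 of that of the group. The lowest of the libraries of those groups, left out in turn, had 0.782 and 0.863, although the PC1 of JH3 baseline replicate 4 was within the limits of both. The other JH3 baseline libraries had -0.05 to 0.384 at 6 h and -0.0818 to 0.321 at 24 h, so replicate 4 was above all of them at 24 h. A sample from outside these groups was not tested, nor was a biological explanation, and without this library 2482 genes differed between the baselines.

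Ribosomal protein genes shifted together, with medians of 0.40, 0.46 and 0.24 after 30 min, 6 h and 24 h of JH3, -0.24 and -0.41 after 30 min and 24 h of 20E, and 0.0004 after 6 h of 20E, where the set was not called, with no member called at any of these times and no set past the threshold with an estimated correlation (adjusted p from 0.527 to 0.992). Their median length was 1896 bases against 4111 for all tested genes. With the length trend of other genes as a covariate the share of the median left was 0.1927 at 30 min and 0.2422 at 6 h of JH3, and 0.2509 at 30 min and 0.0847 at 24 h of 20E, so the length trend may account for most of the size of these medians. With the length trend of all genes as a covariate the set lost its camera call at 24 h of 20E (adjusted p = 0.6435). At the other times where it was called, it still passed camera with the preset correlation. Within runs B and C the medians after 20E were smaller, -0.04 at 30 min (adjusted p = 0.609 by camera) and -0.15 at 24 h (0.3). Those after JH3 were larger there, 0.58, 0.75 and 0.33 at 30 min, 6 h and 24 h. At 24 h of JH3 the share left with the length trend was 1.4377, which argues against that trend there, and the hormone stays open as an untested explanation at each time.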

How the results depend on the processing

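The alternatives with voom, with the length trend and without the libraries that stood apart, and the extra contrasts with the other baseline, were chosen only after the results had been seen. Of 257 results for named genes 144 were called, none changed sign while called, and 126 of these stayed called under every alternative fixed in advance that kept all libraries in place. Over all alternatives a call was lost in 340 cases and gained in 38; in 258 of the 3111 cases called in neither fit the sign was the other one. With pseudocounts, filters and median-ratio rescaling all counts stayed within 1.5 times the reported ones.

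Counts that moved by more were as follows, with the cause not tested unless fewer libraries are named. Library weights gave 3177 genes between the baselines, 216 and 2016 at 6 h and 24 h of 20E, 9 and 55 at 6 h and 24 h of JH3, 126 and 751 for the difference and 67 and 426 for the mean. Without the run term 24 h of JH3 gave 61 and the mean at 24 h 399, and with 2 sets of runs 51 and 347. Quantile normalization gave 15 at 24 h of JH3. Voom gave 8 at 6 h of JH3. With the length trend 6 h of 20E gave 76, 6 h and 24 h of JH3 gave 12 and 236, the difference 36 and 635 and the mean 59 and 454. Without the 2 libraries that stood apart 24 h of JH3 gave 38 and the difference at 6 h 37. Fewer libraries entered within run A (163 between the baselines, 4 and 1 at 6 h of 20E and of JH3, 1 for the difference and 2 for the mean at 6 h), within runs B and C (1067, 16 and 272 for 20E, 2 and 6 for JH3, 2 for the difference at 6 h, 5 and 68 for the mean) and with only the compared groups fitted (692, 3 and 7 for JH3, 15 and 186 for the difference). The fits of only the compared groups also replaced or dropped the run term, so fewer libraries were not their only change. Of 26 lists called over the 7 comparisons 2 stayed called with an estimated correlation. These were the ecdysone response and cytochrome P450 lists at 6 h of 20E, which share Cyp18a1. Lists were not run with voom or without single libraries. The covariance with the baseline difference was 0.1369 and 0.0823 for 20E and JH3 added with a pseudocount of 0.1, and 0.1522 and 0.0855 with voom.

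With the replicate number as a replicate block 6 h of 20E gave 32 genes and 24 h of JH3 gave 15, and other counts stayed within 1.5 times. The labels do not say that a number marks a day or batch, 42 of 105 pairs with the same number had a correlation over 0.1 (mean 0.0086, against -0.0008 for different numbers) and 8 of 35 libraries correlated best with their own number, so the numbers were not taken to pair the cultures.

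Leaving out single libraries gave 1219 to 2482 genes between the baselines, 0 to 0, 30 to 55 and 337 to 542 at 30 min, 6 h and 24 h of 20E, and 0 to 129, 4 to 6 and 12 to 54 for JH3. The difference ranged over 0 to 24, 15 to 36 and 195 to 399, and the mean over 0 to 0, 16 to 25 and 127 to 222. The lowest and highest of these came without JH3 baseline replicates 3 and 4 for the baselines, without replicate 1 of the 24 h group and JH3 baseline replicate 4 at 24 h of 20E, without replicate 1 of the 30 min group at 30 min of JH3, and without replicates 2 and 1 of the 24 h group at 24 h of JH3. Correlations of the switches ranged over -0.3775 to -0.0160, -0.2604 to 0.1773 and -0.0607 to 0.1725, and covariances over 0.0734 to 0.1243 and 0.0380 to 0.0655.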

Other observations

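The length trends of the splits were looked up only after those splits had been seen. Most genes that rose at 6 h also rose at 24 h. Of the 47 genes that rose after 6 h of 20E, 45 also rose after 24 h (1.49 for independent lists) and 25 were higher in the 20E baseline (4.56). The 5 genes that rose after 6 h of JH3, Kr-h1, Sidpn, cwo, Pino and LOC105192299, all rose after 24 h, and 4 of the 5 were lower in the 20E baseline (0.572). After 24 h 4 genes rose in both switches (0.636). The lists share baseline libraries, which adds to each overlap but the last.

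Other splits of the same libraries were counted for each result. The numbers of splits as large include the real one and were not corrected for the number of results. For the baselines (2088 genes; highest other split 1838, with 20E baseline replicate 3 set beside the 4 JH3 libraries) 1 of 100 was as large. For 20E at 24 h (515; 25) it was 1 of 35. No other split tried reached the real count in these results, which argues against chance there. Elsewhere some other splits called more genes than the real groups, so the splits do not exclude chance. This held for 20E at 6 h (50; 109), with 2 of 100, and for JH3 at 6 h (5; 1747), with 4 of 100. It also held for JH3 at 24 h (24; 318), with 4 of 56. For the difference there were 3 of 100 at 6 h (23; 3031) and 2 of 100 at 24 h (298; 367). For the mean there were 2 of 100 at 6 h (25; 1293) and 3 of 100 at 24 h (193; 313). At 30 min limma called 0 genes in each result, with unadjusted counts of 168 for 20E, 1008 for JH3, 936 for the difference and 294 for the mean, and 0 by voom. Each split then calls at least as many genes by construction (100 of 100, and 56 of 56 for JH3), so the splits say nothing about chance there. The highest others were 121 for 20E, 670 for JH3, 432 for the difference and 1432 for the mean.

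Splits with several times the real count point to a structure of the libraries. For 20E cultures the mean length trend was 0.0509 in the first part and -0.0824 in the second in the split that called 1747 genes, against -0.0396 and 0.0081 in the real groups. It was -0.0974 and 0.0340 in the split that called 670 (real groups -0.0542 and 0.0081), and 0.0827 and -0.0102 in the one that called 318 (0.0523 and 0.0081). For JH3 cultures it was -0.0299 and 0.0294 in the split that called 121 (0.0201 and -0.0331). In the split that called 109 it was 0.0039 and -0.0335, close to the 0.0036 and -0.0331 of the real groups, so the length trend does not set that split apart.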
